A study of Mus musculus with 20 samples.

How the data were processed

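Messenger RNA of mouse liver was sequenced in a design of 2 diets by 2 antibodies. The mice were C57BL/6, fed either regular chow or a diet deficient in methionine and choline (MCD), which per the labels models steatohepatitis. They received either an antibody against acyl-CoA binding protein (ACBP, the product of the Dbi gene) or an IgG isotype control. The labels list 20 samples, 5 in each of the 4 groups, and groups were taken from the diet and treatment labels. The labels give no sex, age, sampling time or batch. Per the labels' protocols, RNA was extracted with a column kit and the mRNA libraries were strand-specific.

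The submitters' processing notes name HISAT2 2.2.1 for alignment, HTSeq 0.13.5 for counting, DESeq2 without a version, and the mouse build mm39. The authors deposited 2 tables, 1 per diet, each titled as a DESeq2 table per the file headers, with 54325 genes. Each table gives the authors' comparison of anti-ACBP with IgG. The deposited signal columns are normalized counts (read counts divided by size factors), given as a mean over all libraries and as a mean per group. The authors' fold change column is on a log2 scale, anti-ACBP over IgG, with its standard error (SE), and ends at -5 and 5, values that 30 genes reach on MCD and 28 on chow. The deposited p-value columns hold a Wald p and a Benjamini-Hochberg adjusted p-value, both rounded to 6 decimals. A p that the tool did not give is listed as 1. An adjusted p was present for 20265 genes on MCD and 14618 on chow. The lowest mean normalized count with an adjusted p was 2.49 on MCD and 12.85 on chow. The p was withheld for 36 genes on MCD and 46 on chow that had a mean above 0 and a fold change.

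Values per library were not used here, so the count models planned before the data were examined, including a joint model of both diets, were not fitted. The antibody comparisons are therefore those of the authors' deposited tables, and the design could not be refitted with libraries left out. Genes changed by the antibody are those with an adjusted p under 0.05. Deposited values from 0.001 up were taken as they stand, and smaller ones were recomputed from the deposited fold change and SE, which changed 0 calls. For a gene at -5 or 5 the recomputed p rests on that end value.

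The mean depth behind a gene is its normalized count. Group columns summed to 34621779 (IgG) and 39398190 (anti-ACBP) normalized counts on MCD, and to 38600264 and 35093280 on chow. CPM below stands for a gene's mean normalized count scaled to a column total of 1000000, computed here. Genes seen in 1 read of 1 library share a few exact mean values, which show how many libraries a table averages and their size factors. The MCD table shows 10 such values, 5 per group, with size factors from 0.839 to 1.08. The chow table shows 8, 4 per group, with size factors from 0.905 to 1.11, while the labels list 5 per group. Which animals stand behind the chow means is not known here. The median SE of a log2 fold change, over genes at a CPM of 5 or more, was 0.118 in both tables.

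The difference of the antibody effect between diets was computed here as the difference of both deposited log2 fold changes, over the square root of the summed squared SEs, with a normal p, Benjamini-Hochberg adjusted over the 14607 genes tested in both tables. On simulated fold changes with the deposited SEs and 200 of 14607 genes changed, this test recovered 64.8% of differences of 1 on the log2 scale and 90.1% of differences of 2. Of its calls, 5.1% and 4.3% were false. The simulated values were normal with the deposited SEs, so these rates do not test whether either assumption holds in the data.

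The tables were scaled separately, so MCD and chow were compared as levels, without a test. The log2 ratio of group means was centred on its median over the 9098 genes at a CPM of 5 or more in both tables, which was 0.24 for the IgG groups and 0.29 for the anti-ACBP groups. Group means under 3 normalized counts were set to 3 when genes were ranked by this ratio. The relation of this ratio to the antibody effect on MCD uses the same MCD IgG libraries in both values. The value with no antibody effect was therefore simulated 200 times from the deposited SEs, independently for each gene.

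A set of 34 gene lists was fixed before the data were examined, and 5 lists were added afterwards (female-biased liver genes, ribosomal proteins, proteasome, complement and coagulation, urea cycle and amino acid catabolism). The female-biased list was written after some such genes had been seen, among them Sult1e1 and Abcd2, which it leaves out, and before it was tested. Lists were tested with cameraPR of limma 3.58.1 in R 4.3.3 on the deposited Wald statistics, with a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, separately for the fixed and the added lists. A correlation of 0.05 stands in for an estimated correlation, which needs values per library. On simulated statistics of 14618 independent genes for chow, with 28 genes shifted by 1 SE, the test recovered 94% of shifted lists. Of other lists 0.125% passed, a rate that does not cover lists whose members vary together. Symbols were matched by name, 1 member each of the matrix and immediate early lists through a newer symbol. In the red blood cell and the complement and coagulation lists 1 member each was not matched.

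Named genes follow a rule fixed before the data were examined. It takes Dbi, the 10 highest and 10 lowest fold changes of each comparison among changed protein-coding genes at a CPM of 5 or more with a standard symbol, up to 4 members with the smallest p of each list discussed and of the difference between diets, and the sex chromosome genes. Some genes that the rule takes are not reported here, and counts include them. Diet has no test, so the rule could not be applied to it as fixed. Its genes were taken by the size of the centred ratio, among protein-coding genes at a CPM of 5 or more on average over both tables. This form replaced a first one, which asked for that level in each table, after the genes it named had been seen, so the diet genes are not a choice made blind to their values. The Mup, Saa, Cyp2a, Cyp2b, Cyp3a, Cyp4a and Acot families hold near-identical copies whose reads the counting may have split, so values of single members are uncertain.

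The alternatives tried were other filters, a fold change threshold, other scalings, restored p-values, removal of a trend on GC content and transcript length (GENCODE M21 transcripts matched by symbol, 99.2% of genes on MCD and 99.5% on chow) and a stricter list test. No coordinates are given, as the reference at hand is of another build than the authors'. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.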

Results

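Liver mRNA was sequenced from C57BL/6 mice in 4 groups: regular chow with IgG, chow with anti-ACBP, MCD diet with IgG, and MCD diet with anti-ACBP. ACBP is an acyl-CoA carrier that is also released from cells, and the antibody neutralizes it. The MCD diet lacks methionine and choline and produces fat accumulation, inflammation and fibrosis in the liver. The labels list 5 samples per group. The means on MCD rest on 5 libraries per group and those on chow on 4, read from the single-read steps of the tables. Column totals ran from 34621779 to 39398190 normalized counts. Group levels, log2 fold changes and their SEs for the antibody effect are those of the authors' deposited tables throughout. So are its gene-wise adjusted p-values from 0.001 up. Smaller ones were recomputed here from the deposited fold changes and SEs. List tests, ratios between diets and tests between diets were computed here.

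Dbi, which encodes the antibody's target, rose with anti-ACBP on MCD and did not pass the test on chow. In the authors' deposited tables its mean was 13686 normalized counts in MCD IgG and 23709 in MCD anti-ACBP. The log2 fold change there was 0.79 ± 0.097 (SE, recomputed adjusted p = 1.12e-14). On chow the mean was 24311 with IgG and 24526 with anti-ACBP, a log2 fold change of 0.01 ± 0.087 (adjusted p = 0.952). The difference between diets was 0.78 ± 0.13 (adjusted p = 8.28e-08). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty stood at 1720, 1463, 501.9 and 383 normalized counts in MCD IgG and at 1850, 1871, 526.9 and 375 in MCD anti-ACBP. On chow they stood at 1538, 1771, 558 and 380 with IgG and at 1577, 1831, 503 and 347 with anti-ACBP. Xist, expressed from the inactive X of females, had means of 9.55, 2.72, 9.17 and 4.62 in the groups MCD IgG, MCD anti-ACBP, chow IgG and chow anti-ACBP. Of these 5 genes Eif2s3y rose on MCD, by 0.35 ± 0.137 (adjusted p = 0.0338), and the others did not pass the test there. The list of these 5 genes gave adjusted p = 0.788 in the list test on MCD and, with 4 tested, 0.883 on chow (1 rose on MCD and 0 on chow, also when adjusted over the list alone).

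The first comparison asks what the neutralizing antibody changed in livers on the MCD diet. Most genes on the lists of extracellular matrix, cytokines and macrophage markers fell, and most of those on the lists of male-biased and hepatocyte genes rose. Of 20265 genes tested in the authors' deposited table, 6261 changed (30.9%), 2973 of them higher and 3288 lower with anti-ACBP. Among the 2151 that changed by at least 1 on the log2 scale, 641 were higher and 1510 lower. Relative to column totals, a scaling that moves every fold change on MCD down by 0.19, the split became 1398 higher and 5468 lower of 6866.

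The 10 highest genes on MCD were Mup19, Mup7, Ugt2b38, Mup16, Serpina1e, Hsd3b5, Mup3, Chrna4, Elovl3 and Mup14. Of these, 5 encode major urinary proteins, pheromone carriers that male mouse liver secretes. In the authors' deposited table Mup19 went from a mean of 564 to 20530 normalized counts, at the upper end of the fold change column. Mup3 went from 7303 to 101155, a log2 fold change of 3.79 ± 0.22 (adjusted p = 3.59e-60). Serpina1e, an alpha-1-antitrypsin paralog, went from 449 to 8534 (4.25 ± 0.30, adjusted p = 1.39e-42). The steroid dehydrogenase Hsd3b5 rose from 227 to 3623 normalized counts and the fatty acid elongase Elovl3 by 3.39 ± 0.62 on the log2 scale. Ugt2b38, a glucuronosyltransferase, rose by 4.55 ± 0.52, and Chrna4, a nicotinic receptor subunit, by 3.43 ± 0.50. Mup7, Mup16 and Mup14 rose by 4.81 ± 0.69, 4.45 ± 0.41 and 3.37 ± 0.50. Reads of Mup copies are hard to tell apart, so the single Mup values are uncertain.

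Among the 10 lowest genes on MCD were Sprr1a, Sult1e1, Ly6d, Lcn2, Gpnmb, Mmp12, Ubd, Lgals3 and Cdkn1a. The first 4 reached the lower end of the authors' deposited fold change column. Sprr1a, a cornified envelope protein, fell from a mean of 642 to 3.03 normalized counts, and the estrogen sulfotransferase Sult1e1 from 5152 to 25.7. Ly6d fell from 2837 to 48.0, and Lcn2, an iron-siderophore binding protein of the acute phase, from 8024 to 213. Gpnmb, Mmp12 and Lgals3 are expressed by lipid-associated macrophages, and had log2 fold changes of -4.58 ± 0.21, -4.42 ± 0.28 and -3.62 ± 0.24. Ubd, a ubiquitin-like modifier, stood at -4.39 ± 0.30 and the cell cycle inhibitor Cdkn1a at -3.44 ± 0.44.

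**Figure D1:**
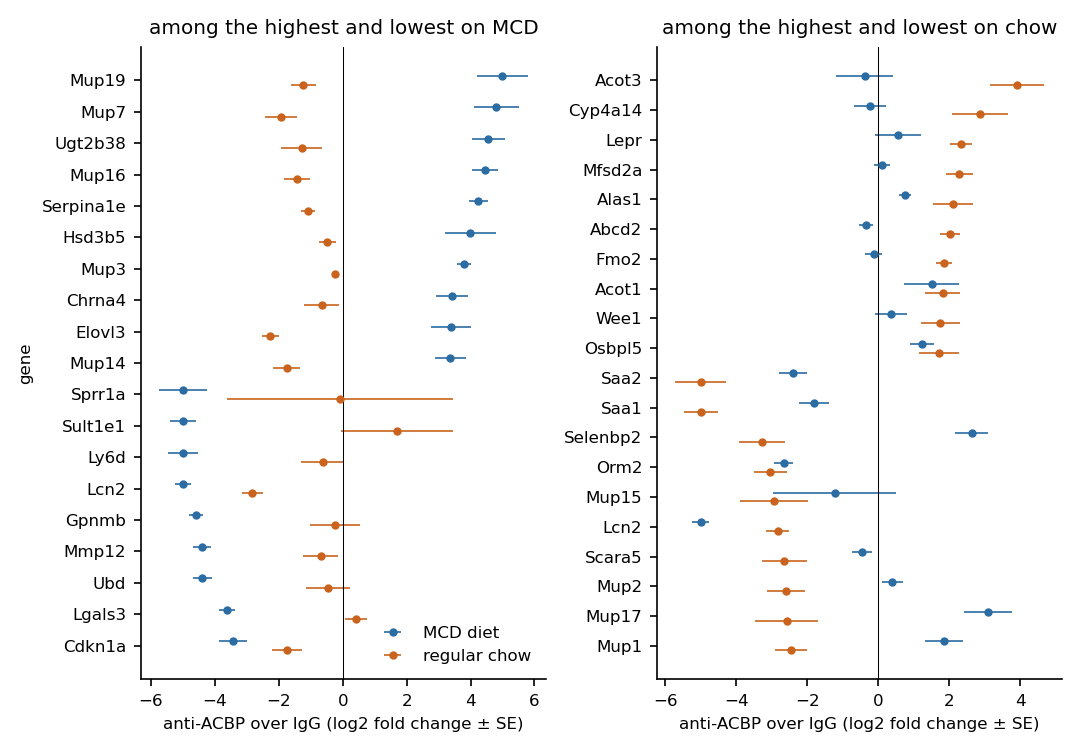
Log2 fold change of anti-ACBP over IgG (x axis) with its SE (bars), from the authors' deposited tables, for genes among the 10 highest and 10 lowest on MCD (left) and on chow (right). Each gene (y axis) is shown on MCD (blue) and chow (orange). Mup3 stood at 3.79 on MCD and at -0.26 on chow.

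Fibrosis and inflammation lists fell on MCD. Of 35 extracellular matrix and fibrosis genes, 34 fell and 1 rose (34 and 1 adjusted over the list alone; list test adjusted p = 1.88e-26), with a median log2 fold change of -1.10. Mmp12, the protease inhibitor Timp1, the basement membrane collagen Col4a1 and the collagenase Mmp13 had log2 fold changes of -4.42 ± 0.28, -3.82 ± 0.35, -1.86 ± 0.18 and -3.57 ± 0.37 in the authors' deposited table. Of 27 tested cytokines and chemokines 24 fell and 1 rose (24 and 1 adjusted over the list alone; list test adjusted p = 4.56e-24). These included the monocyte chemoattractant Ccl2 (-3.27 ± 0.29), its receptor Ccr2 (-2.47 ± 0.22), Tlr2 (-2.41 ± 0.21) and Tnfaip3 (-1.86 ± 0.18). Of 22 macrophage markers 17 fell and 1 rose (17 and 1 adjusted over the list alone; list test adjusted p = 1.88e-26), with Trem2 at -3.07 ± 0.19 and Itgax at -3.25 ± 0.20. Of 20 interferon response genes 16 fell and 1, Bst2, rose (16 and 1 adjusted over the list alone; list test adjusted p = 1.04e-07). Gbp2 stood at -1.53 ± 0.14 and Rsad2 at -2.26 ± 0.31. Neutrophil markers were tested for 6 genes, of which 3 fell (5 adjusted over the list alone; list test adjusted p = 0.0303, and adjusted p = 0.0558 with a correlation of 0.05 and 0.0898 relative to column totals).

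Stress and proliferation lists fell as well. Of 24 cell cycle genes 20 fell and 1 rose (21 and 1 adjusted over the list alone; list test adjusted p = 4.52e-08), among them the kinase Plk1 (-2.15 ± 0.32) and the proliferation marker Mki67 (-1.78 ± 0.29). Of 20 NRF2 targets, antioxidant and detoxifying genes, 13 fell and 1 rose (14 and 1 adjusted over the list alone; list test adjusted p = 3.56e-07). Haem oxygenase Hmox1 stood at -1.90 ± 0.19, Srxn1 at -2.18 ± 0.25, the cystine transporter Slc7a11 at -2.56 ± 0.32 and Nqo1 at -1.39 ± 0.19. Of 20 apoptosis genes 11 fell and 1 rose (14 and 1 adjusted over the list alone; list test adjusted p = 3.63e-05), and of 16 immediate early genes 11 fell and 0 rose (11 and 0 adjusted over the list alone; list test adjusted p = 1.41e-04). Pmaip1 stood at -1.88 ± 0.21 and Egr1 at -1.97 ± 0.25. In the ER stress and ATF4 list 7 of 21 fell and 5 rose (8 and 5 adjusted over the list alone), and the list test did not pass (adjusted p = 0.225). The stress-induced factors Atf3, Trib3 and Nupr1 fell there, with log2 fold changes of -3.35 ± 0.27, -2.27 ± 0.29 and -2.80 ± 0.42, and the chaperone partner Sdf2l1 rose by 0.84 ± 0.19.

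The series title names autophagy, the degradation of cell contents in lysosomes, and both parts of that route were examined on MCD. Of 34 autophagy genes in the authors' deposited table, 13 rose and 2 fell (15 and 2 adjusted over the list alone). The list test gave adjusted p = 0.00189, with a median of 0.22 that was 0.03 relative to column totals, where the list no longer passed (adjusted p = 0.0514). Atg9a, Ulk2 and Wipi1 rose, by 0.46 ± 0.072, 0.80 ± 0.13 and 0.62 ± 0.12, and the autophagy receptor Sqstm1 fell by 1.11 (SE 0.17). These are mRNA levels, and degradation itself was not measured. Of 28 lysosome genes 16 fell and 2 rose (17 and 2 adjusted over the list alone; list test adjusted p = 1.17e-05), among them Cd63 (-2.02 ± 0.22), Psap (-0.78 ± 0.10) and the cathepsin Ctsb (-0.61 ± 0.080). Macrophage markers fell in the same comparison.

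Several lists of genes that hepatocytes express moved the other way on MCD. Of 14 male-biased liver genes 13 rose and 0 fell (13 and 0 adjusted over the list alone; list test adjusted p = 2.19e-19), with a median of 2.06. Besides Mup3 and Serpina1e they included the organic anion transporter Slco1a1 (2.92 ± 0.21) and Nudt7 (1.87 ± 0.21). Of 22 tested lipogenesis genes 11 rose and 1 fell (12 and 1 adjusted over the list alone; list test adjusted p = 2.75e-04). The stearoyl-CoA desaturase Scd1 rose by 2.80 ± 0.52, malic enzyme Me1 by 1.51 ± 0.15 and Mlxipl by 0.92 ± 0.13, and Pgd was the member that fell. Of 24 cholesterol synthesis genes 9 rose and 0 fell (9 and 0 adjusted over the list alone; list test adjusted p = 0.00296), among them Tm7sf2 (1.34 ± 0.21) and Stard4 (0.97 ± 0.15). Of 27 fatty acid oxidation genes 11 rose and 0 fell (11 and 0 adjusted over the list alone; list test adjusted p = 5.10e-04), with Acsl1 at 1.19 ± 0.18 and Acaa2 at 0.82 ± 0.11. The median of this list, 0.28, lay above those of only 89.52% of 10000 random lists matched on mean expression. Of 23 PPARalpha targets 4 rose and 5 fell (4 and 5 adjusted over the list alone; list test adjusted p = 0.978). The fatty acid binding protein Fabp1 rose by 1.75 ± 0.17 and the glycerol channel Aqp7 fell by 3.17 (SE 0.39).

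Of 20 genes of bile acid synthesis and transport 9 rose and 2 fell on MCD (9 and 2 adjusted over the list alone; list test adjusted p = 7.91e-04), among them the bile acid importer Slc10a1 (1.65 ± 0.17) and Slc27a5 (1.31 ± 0.15). Of 22 xenobiotic metabolism genes 12 rose and 1 fell (12 and 1 adjusted over the list alone; list test adjusted p = 1.47e-04), with Cyp2c54 at 2.65 ± 0.49 and Ces2a at 1.59 ± 0.18. Of 20 glucose metabolism genes 10 rose and 3 fell (10 and 3 adjusted over the list alone; list test adjusted p = 0.0230, and adjusted p = 0.0869 with a correlation of 0.05). Glycogen phosphorylase Pygl rose by 1.09 ± 0.15. Of 22 genes of methionine and choline metabolism, the nutrients the diet lacks, 5 rose and 6 fell (5 and 6 adjusted over the list alone; list test adjusted p = 0.954). Bhmt, which remethylates homocysteine, stood at -2.24 ± 0.30 and choline kinase Chka at -1.42 ± 0.22. In the acute phase list 11 of 22 fell and 6 rose (11 and 6 adjusted over the list alone; list test adjusted p = 0.0189, and adjusted p = 0.0839 with a correlation of 0.05). Lcn2 and Orm2 fell, and the fibrinogen chains Fgb and Fgg rose by 0.64 ± 0.089 and 0.78 ± 0.12.

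Markers of cell types did not move together on MCD. Of 16 hepatocyte markers 9 rose and 1 fell (10 and 1 adjusted over the list alone; list test adjusted p = 0.00152), with transthyretin, Ttr, at 0.78 ± 0.12 and Apoa1 at 0.55 ± 0.091. Of 13 sinusoidal endothelial markers 2 rose and 1, Lyve1, fell (2 and 1 adjusted over the list alone; list test adjusted p = 0.865). Of 11 tested cholangiocyte markers 5 fell (7 adjusted over the list alone; list test adjusted p = 0.00974), with Krt23 at -1.60 ± 0.29. Of 15 T and NK cell markers 1, Gzma, fell (1 adjusted over the list alone; list test adjusted p = 0.218), and of 10 B and plasma cell markers 0 passed (0 adjusted over the list alone; list test adjusted p = 0.947). Red blood cell genes were higher for 5 of 7 (5 adjusted over the list alone; list test adjusted p = 0.0661), with Alas2 at 0.80 ± 0.21. Of 5 adipocyte markers 2, Car3 and Adrb3, rose and 1, Plin4, fell (2 and 2 adjusted over the list alone; list test adjusted p = 0.5001). Of 5 pancreatic acinar markers Cela1 rose and Amy2a5 fell (1 and 1 adjusted over the list alone; list test adjusted p = 0.841), and of 4 skeletal muscle markers 0 passed (0 adjusted over the list alone; list test adjusted p = 0.760).

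Some clock genes, which run the daily rhythm of the liver, rose and some fell on each diet. Their list test, which looks for a shift of the whole list in a single direction, did not pass. On MCD 4 of 19 rose and 2 fell (4 and 2 adjusted over the list alone; list test adjusted p = 0.184). In the authors' deposited table the activators Npas2 and Arntl had log2 fold changes of -2.03 ± 0.53 and -1.79 ± 0.49, and Dbp and the repressor Cry1 rose by 0.70 ± 0.19 and 0.69 ± 0.20. On chow 4 of 18 rose and 4 fell (5 and 4 adjusted over the list alone; list test adjusted p = 0.989), with Arntl at -3.10 ± 0.41, Nr1d1 at -1.54 ± 0.13, Clock at -0.97 ± 0.098 and Per1 at 0.997 ± 0.127.

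**Figure D2:**
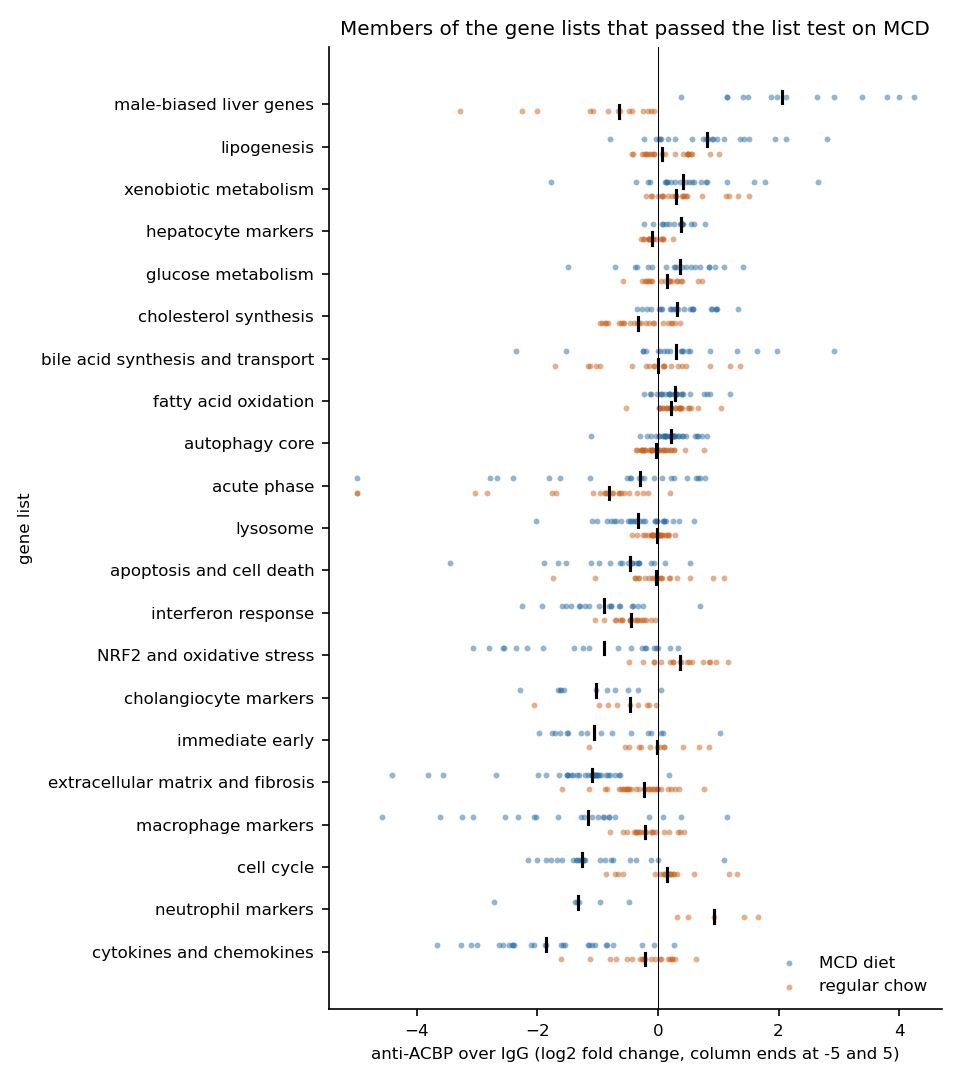
Log2 fold change of anti-ACBP over IgG (x axis, from the authors' deposited tables) of each tested member (points) of the 21 gene lists (y axis) that passed the list test on MCD. Blue points are the MCD diet, orange points regular chow, and black bars the median of a list on that diet. The male-biased list has medians of 2.06 on MCD and -0.65 on chow, and the NRF2 list -0.90 and 0.37.

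The second comparison asks what the antibody changed in livers on regular chow. The lists of acute phase and male-biased genes passed the list test as lower, and those of fatty acid oxidation, PPARalpha targets and xenobiotic metabolism as higher. Of 14618 genes tested in the authors' deposited table, 1761 changed (12%), 816 higher and 945 lower with anti-ACBP. Among the 304 that changed by at least 1 on the log2 scale, 106 were higher and 198 lower. Relative to column totals, which moves every fold change on chow up by 0.14, 3138 changed, 2605 of them higher and 533 lower.

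The 10 highest genes on chow were Acot3, Cyp4a14, Lepr, Mfsd2a, Alas1, Abcd2, Fmo2, Acot1, Wee1 and Osbpl5. In the authors' deposited table the acyl-CoA thioesterase Acot3 went from a mean of 167 to 2506 normalized counts. Its log2 fold change was 3.91 ± 0.75 (recomputed adjusted p = 1.17e-05). The fatty acid hydroxylase Cyp4a14 rose by 2.87 ± 0.80, the leptin receptor Lepr by 2.33 ± 0.30 and the lysophospholipid transporter Mfsd2a by 2.28 ± 0.38. Alas1, the first enzyme of haem synthesis, rose by 2.11 ± 0.57 and the peroxisomal transporter Abcd2 by 2.02 ± 0.29. Fmo2, Acot1, the kinase Wee1 and Osbpl5 rose by 1.84 ± 0.22, 1.81 ± 0.49, 1.75 ± 0.55 and 1.71 ± 0.56. The 10 lowest were Saa2, Saa1, Selenbp2, Orm2, Mup15, Lcn2, Scara5, Mup2, Mup17 and Mup1. Serum amyloid A genes Saa1 and Saa2 fell from means of 26601 and 19696 to 755 and 248, the lower end of the fold change column. In MCD IgG livers their means were 2854 and 1921. Selenbp2 stood at -3.28 ± 0.64, the acute phase glycoprotein Orm2 at -3.04 ± 0.45, Lcn2 at -2.83 ± 0.33 and the ferritin receptor Scara5 at -2.65 ± 0.63. Mup15, Mup2, Mup17 and Mup1 fell, with log2 fold changes of -2.95 ± 0.96, -2.61 ± 0.53, -2.58 ± 0.88 and -2.46 ± 0.46, with the same uncertainty among copies.

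Of 22 acute phase genes 19 fell and 0 rose on chow (19 and 0 adjusted over the list alone; list test adjusted p = 1.77e-38), including Orm1 (-1.09 ± 0.11) and haemopexin, Hpx (-0.88 ± 0.10), in the authors' deposited table. Of 27 fatty acid oxidation genes 12 rose and 1 fell (17 and 1 adjusted over the list alone; list test adjusted p = 8.29e-08), with Acadl at 0.55 ± 0.10. Of 21 tested PPARalpha targets 11 rose and 0 fell (12 and 0 adjusted over the list alone; list test adjusted p = 2.16e-06), with Acot2 at 1.63 ± 0.33 and Aldh3a2 at 0.67 ± 0.14. Of 22 xenobiotic metabolism genes 10 rose and 0 fell (11 and 0 adjusted over the list alone; list test adjusted p = 1.62e-09). The cytochrome P450 reductase Por rose by 1.32 ± 0.17 and Cyp2a5 by 1.51 ± 0.20. Of 18 tested NRF2 targets 7 rose and 0 fell (8 and 0 adjusted over the list alone; list test adjusted p = 6.47e-04), with Nqo1 at 0.84 ± 0.17. Of 14 male-biased genes 9 fell and 0 rose (9 and 0 adjusted over the list alone; list test adjusted p = 2.74e-09), among them Elovl3 (-2.26 ± 0.26) and Ces4a (-2.01 ± 0.31).

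Further lists that passed on chow were lower with anti-ACBP. Of 20 interferon response genes 6 fell (9 adjusted over the list alone; list test adjusted p = 1.36e-06), with Rsad2 at -1.05 ± 0.20. Of 31 tested extracellular matrix genes 7 fell and 1, Pdgfra, rose (8 and 1 adjusted over the list alone; list test adjusted p = 0.00231), with Col3a1 at -0.87 ± 0.15 and Col1a1 at -1.15 ± 0.22. Of 24 cholesterol synthesis genes 8 fell and 1 rose (10 and 1 adjusted over the list alone; list test adjusted p = 0.00355), with squalene epoxidase Sqle at -0.94 ± 0.23. Of 13 mitochondrially encoded genes 5 fell (5 adjusted over the list alone; list test adjusted p = 7.30e-04), with mt-Co1 at -0.34 ± 0.079. On MCD 2 of these 13 rose (2 adjusted over the list alone; list test adjusted p = 0.760). The autophagy list did not pass on chow (adjusted p = 0.713): Bnip3 rose by 0.76 ± 0.093, 5 members fell (1 and 5 adjusted over the list alone), and the median of -0.03 became 0.10 relative to column totals. The lysosome list did not pass either (adjusted p = 0.465), and Ctsl was the single member that fell, by 0.43 (SE 0.10).

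Lists of other processes did not pass the list test on chow. These were lipogenesis (6 of 23 rose and 1 fell, adjusted p = 0.111), bile acid genes (4 of 20 rose and 3 fell, 0.989), cytokines and chemokines (2 of 21 fell, 0.274), ER stress and ATF4 (1 of 21 rose and 6 fell, 0.0669), methionine and choline metabolism (3 of 22 rose and 7 fell, 0.111), glucose metabolism (5 of 20 rose, 0.0787), apoptosis (2 of 20 rose and 3 fell, 0.738), cell cycle (3 of 18 rose and 1 fell, 0.316) and immediate early genes (1 of 13 rose, 0.989). Adjusted over the list alone, the counts that rose and fell were, in that order, 8 and 1, 6 and 5, 0 and 2, 1 and 6, 5 and 9, 5 and 0, 3 and 3, 3 and 1, and 1 and 0. The immediate early count leaves out Jun and Nr4a1, whose p was withheld on chow. Their means were 545 and 110 normalized counts with IgG and 1440 and 1007 with anti-ACBP. The SEs of their log2 fold changes were 0.83 and 1.15. Cell type lists that could be tested did not pass on chow. The skeletal muscle list could not be tested there. The p of its members Acta1, Ckm and Myh4, among others, was withheld, and their means are given at the end. Of 5 adipocyte markers 3, Adrb3, Car3 and Cfd, fell (3 adjusted over the list alone; list test adjusted p = 0.120), and of 3 pancreatic acinar markers 1, Cela1, fell (1 adjusted over the list alone; list test adjusted p = 0.111). Of 16 hepatocyte markers 0 passed, of 21 macrophage markers 1 fell, of 13 endothelial markers 1 rose, of 9 cholangiocyte markers 1 fell, of 6 red blood cell genes 1 fell, and of the T and NK, B cell and neutrophil markers 0 passed. Their list test adjusted p-values were 0.262, 0.119, 0.0787, 0.0787, 0.290, 0.989, 0.743 and 0.178 in that order. Adjusted over the list alone, 1 T and NK cell marker fell, 0 endothelial markers passed, and the other counts were the same.

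The third comparison asks whether the antibody effect depended on the diet. It did for 3394 of the 14607 genes tested in both authors' deposited tables, with the effect higher on MCD for 1847 and lower for 1547. Relative to column totals the split became 717 higher and 4721 lower of 5438. The 4 genes with the smallest p were Mup3 (difference 4.05 ± 0.24, adjusted p = 1.07e-60), Serpina1e (5.33 ± 0.37), Slco1a1 (2.99 ± 0.24) and C8b, a subunit of the membrane attack complex (2.40 ± 0.20). Mup3, Serpina1e and C8b rose on MCD and fell on chow. In the male-biased list 13 of 14 genes had a higher effect on MCD and 0 a lower one (13 and 0 adjusted over the list alone; list test adjusted p = 1.29e-31). In the NRF2 list 12 of 18 had a lower effect on MCD and 0 a higher one (13 and 0 adjusted over the list alone; list test adjusted p = 1.03e-10).

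Among genes tested in both, 809 changed on both diets. Of these 275 were higher on both (159.3 if the lists were independent), 232 lower on both (167.3), 227 higher on MCD and lower on chow (183.9), and 75 lower on MCD and higher on chow (144.9). The comparisons share no libraries. Across 9086 genes the antibody effects on both diets had Pearson's r = 0.072 and Spearman's rho = 0.13. These are correlations across genes, which are not independent replicates.

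The fourth comparison sets MCD beside chow, as levels without a test, because the tables were scaled separately and diet and table coincide. Under IgG, 5 of 13 macrophage markers at a CPM of 5 or more stood at least 2 times higher on MCD after centring and 0 lower, and 5 of 5 red blood cell genes stood at least 2 times lower. In the authors' deposited tables high ratios belonged to Cyp2a4 (31311 normalized counts on MCD and 8.67 on chow), Cyp2b9 (5213 and 0.82), Sult1e1 (5152 and 0.55), Gpnmb (6629 and 5.24) and Mmp12 (3881 and 11.1). They were followed by Cyp2a22 (5925 and 23.7), the transporter Slc22a27 (759 and 5.12), Ly6d (2837 and 28.8) and Vmn2r3 (810 and 11.2). The lowest were Mup17 (95.2 and 100186), Serpina1e (449 and 399981), Mup19 (564 and 499371), Mup7 (1114 and 874356) and Mup15 (12.1 and 1863). Mup14 (2684 and 363361), Mup16 (342 and 36588), Mup9 (433 and 26721), Mup11 (5490 and 322972) and Mup3 (7303 and 378963) completed the 10. Dbi stood at 13686 on MCD and 24311 on chow under IgG, and at 23709 and 24526 under anti-ACBP.

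After centring, 407 of 9098 genes stood at least 2 times higher on MCD than on chow under IgG and 399 at least 2 times lower. Under anti-ACBP these counts were 85 and 56. The centred log2 ratio had an SD over genes of 0.708 under IgG and 0.329 under anti-ACBP. Among extracellular matrix genes at a CPM of 5 or more, 16 of 17 stood at least 2 times higher on MCD under IgG and 4 of 17 under anti-ACBP. All 13 male-biased genes at that level stood at least 2 times lower on MCD under IgG, and 7 of 13 did under anti-ACBP. Relative to column totals, 1008 genes stood at least 2 times higher and 215 lower under IgG. A lower filter, a CPM of 1 or more in both tables, was also used, with the centring on the median of the 9098 genes kept. Of 12154 tested genes, 1169 then stood at least 2 times higher on MCD under IgG and 619 lower. Genes at the ends of the fold change column on MCD were left out. The balance of directions thus depends on the filter as well.

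**Figure D3:**
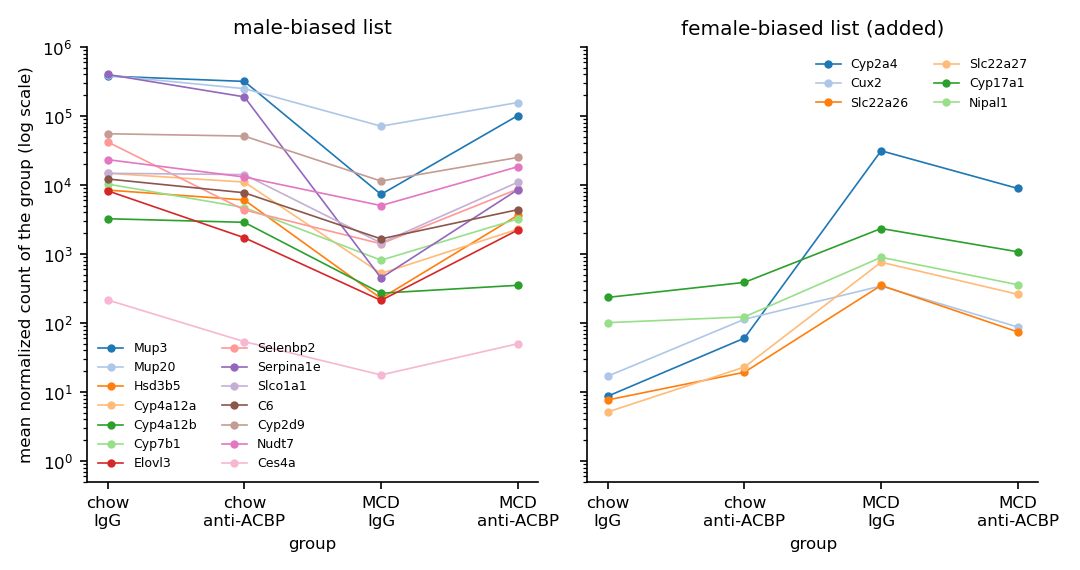
Mean normalized count of each group (y axis, log scale, from the authors' deposited tables, which were scaled separately) for the 14 male-biased genes (left) and the 6 female-biased genes tested on both diets (right, a list added after the data were examined). Lines join the values of a gene over the groups on the x axis, and Serpina1e stood at 399981, 189359, 449 and 8534 from left to right.

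**Figure D4:**
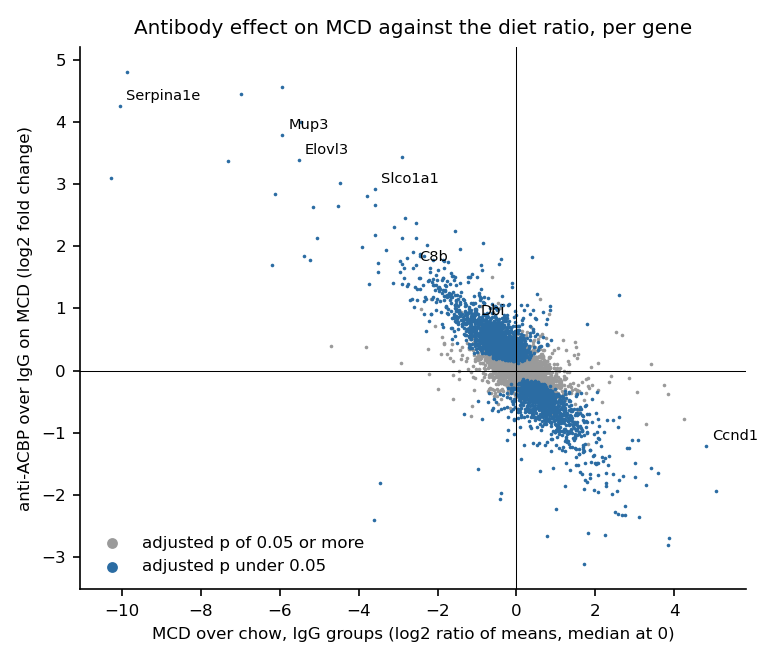
Each point is 1 of 9088 genes at a CPM of 5 or more in both of the authors' deposited tables, genes at the ends of the fold change column left out. The x axis is the centred log2 ratio of MCD over chow in the IgG groups, the y axis the log2 fold change of anti-ACBP over IgG on MCD. Blue genes have an adjusted p under 0.05 for the antibody effect. The points run from the upper left to the lower right, with Pearson's r = -0.792.

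The last comparison asks whether antibody-treated MCD livers lay closer to chow livers. Among genes at least 2 times apart between diets that changed with the antibody, nearly all higher on MCD fell and nearly all lower rose. Of 800 genes at least 2 times apart between diets under IgG, 645 changed with the antibody on MCD in the authors' deposited table, and 640 of them moved against the diet ratio. Of 303 that were higher on MCD 301 fell, and of 342 that were lower 339 rose. Across 9088 genes the antibody effect and the diet ratio had Pearson's r = -0.792 and Spearman's rho = -0.752, with a slope of -0.51. Both values use the MCD IgG libraries, which alone gave a mean r of -0.103 in 200 simulations without an antibody effect, and -0.173 at the lowest. The simulated noise was independent between genes. The covariance was -0.242, against a simulated mean of -0.0106. Against the diet ratio of the anti-ACBP groups, where shared libraries push the covariance above 0, r was -0.401 and the covariance -0.0578. The value computed from the SEs for the shared libraries alone, without a simulation, was 0.0107. The centred log2 ratio to chow IgG had an SD over genes of 0.708 for MCD IgG and 0.447 for MCD anti-ACBP, with 806 and 258 genes at least 2 times apart.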

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

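The tests of an aberrant library and of the gap in calls were set before their results were seen, and the other tests of explanations below were chosen afterwards. The results here are those whose antibody effect differed between diets, as the log2 fold change on MCD minus that on chow, computed from the authors' deposited tables.

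Dbi differed by 0.78. Among genes named for MCD, Mup19 differed by 6.23, Mup7 by 6.75, Ugt2b38 by 5.83, Mup16 by 5.89, Serpina1e by 5.33, Hsd3b5 by 4.47, Mup3 by 4.05, Chrna4 by 4.09, Elovl3 by 5.65 and Mup14 by 5.12. Slco1a1 differed by 2.99 and C8b by 2.40. Lower effects on MCD belonged to Ly6d (-4.37), Lcn2 (-2.17), Lgals3 (-4.04) and Cdkn1a (-1.70). Among genes named for chow, the differences were -4.29 for Acot3, -3.10 for Cyp4a14, -2.18 for Mfsd2a, -2.36 for Abcd2 and -1.97 for Fmo2. They were 2.60 for Saa2, 3.19 for Saa1, 5.91 for Selenbp2, 2.19 for Scara5, 3.004 for Mup2, 5.67 for Mup17 and 4.30 for Mup1. The values of Mup19, Ly6d, Lcn2, Saa1 and Saa2 rest on a fold change at the end of the deposited column.

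Among lists that passed the test of the difference, the median difference was 3.05 for male-biased genes, 0.75 for cholesterol synthesis, 0.49 for acute phase, 0.44 for lipogenesis, 0.42 for bile acid genes, 0.35 for hepatocyte markers and 1.19 for red blood cell markers. It was -1.80 for neutrophil markers, -1.35 for cytokines and chemokines, -1.12 for the cell cycle, -0.87 for macrophage markers, -0.81 for extracellular matrix and -0.76 for PPARalpha targets. It was -0.61 for NRF2 targets, -0.54 for immediate early genes, -0.48 for interferon response, -0.42 for apoptosis and -0.34 for lysosome genes. The autophagy list had a median difference of 0.20, which was -0.12 relative to column totals, so its direction depends on the scaling. With a correlation of 0.05 the difference no longer passed for PPARalpha targets, autophagy, immediate early genes, interferon response, lipogenesis and red blood cell markers. By column totals it no longer passed for PPARalpha targets, autophagy, immediate early genes, interferon response and neutrophil markers, and all medians lay lower by the same amount. Those of cholesterol synthesis, acute phase, lipogenesis, bile acid genes and hepatocyte markers shrank to 0.42, 0.17, 0.11, 0.10 and 0.02, and that of lysosome genes went to -0.66. The hepatocyte median of 0.35 lay above those of only 68.69% of 10000 random lists matched on mean expression.

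On MCD the antibody effects ran against the diet ratios across genes. Noise of the shared MCD IgG libraries that is independent between genes is argued against by the covariance of -0.2416. The lowest of 200 simulated values was -0.0184. Noise that many genes of a library share was not simulated and stays open. A single aberrant IgG library is argued against for 337 of 640 opposed genes, for which it would need a negative count. For 0% of the 640 was the deposited SE as large as it would need. Among the other genes the median SE was 0.143 where 0.64 was needed. Genes called as changed have small SEs by that selection, so the SEs cannot decide it for these other genes. For them a single aberrant library stays open. More than 1 such library, or handling shared by the MCD IgG group, stays open for all, as the labels give no batch and values per library were not used here. An antibody effect that moves MCD livers toward chow levels is a hypothesis that may account for the pattern.

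Of 14 male-biased genes 13 rose on MCD, and 9 fell on chow while 5 did not pass. Reads shared between Mup copies do not account for this, since 11 of 12 members outside the Mup family had a higher effect on MCD. Female animals in a group on MCD as the source of the whole rise are argued against by the Y-linked genes. Their highest 95% upper limit there was 0.623 where 1.028 was needed, a bound set from the male-biased median of 2.06. This bound does not test for a single female in a group on MCD. Female animals in the chow anti-ACBP group are argued against as well: the weighted mean of the Y-linked genes on chow had a lower 95% limit of -0.119, where 1 female among 4 libraries would need -0.415. In the list of female-biased genes, 6 of 6 tested on both diets had a lower effect on MCD than on chow, with a median difference of -3.639. The list holds 18 genes, and the lowest mean tested on chow was 12.85. That mean includes the anti-ACBP group, which favours low genes that rose there, so 6 of 6 cannot stand for the whole list. A change of the sex-biased programme of the liver is a hypothesis that may account for these genes, found and tested on the same data.

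Of the clock genes 6 of 19 passed on MCD, near the share of all tested genes. On chow 8 of 18 passed, where 12% of all tested genes changed. Arntl and Per1 passed on both. Clock gene effects on both diets were compared after the results of all fixed lists had been seen. The list test, which looks for a shift of the whole list in a single direction, did not pass. Over 18 clock genes the antibody effects on MCD and chow had Pearson's r = 0.859 and Spearman's rho = 0.765 (two-sided permutation p = 5e-05, 100000 resamples, genes not being independent), and r = 0.711 without Arntl and Clock. Not all agreed: Nfil3 (0.26 on MCD and -1.16 on chow) and Nr1d1 (-0.12 and -1.54) differed between diets (adjusted p = 9.05e-04 and 0.0173). A change of level of all clock genes is argued against on chow by 2 medians. They were -1.064 over 4 genes that peak around the end of the night and 0.385 over 10 day and evening targets. On MCD the medians were -0.358 over 5 genes, of which 2 fell and 1 rose, and 0.518 over 10. The value of -0.358 is that of Clock, which did not pass (adjusted p = 0.27), so the contrast on MCD is weaker. One shift of the daily phase may account for the genes that agree and leaves Nfil3 and Nr1d1 unexplained, and whether that came from the antibody or from a different time of sampling or feeding is confounded with the groups. The labels give no time.

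The clock pattern replaced another in this weighing, the gap in calls: more genes changed on MCD than on chow. Its 2 tests were chosen after the data had been examined and before their own results were seen. With the statistics reduced to 4 libraries per group, 4816 genes changed on MCD against 1751 on chow among genes tested in both. With the trend on GC content and length removed, 5394 changed against 1680 among the same genes. Neither the number of libraries nor that trend accounted for the gap.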

How the results depend on the processing

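Alternatives that change the scaling, restore withheld p-values, remove the GC and length trend, limit the genes to those tested in both tables, rescale to another number of libraries or use a correlation of 0.05 were chosen after the data were seen. So were those of the correlations, other than the filter for the correlation between both antibody effects. Models refitted from counts with other size factors, other tests or all libraries together, other pseudocounts, each library left out, splits of the IgG libraries and list tests with an estimated correlation need values per library and were not run. No paired analysis was possible because the group columns carry no replicate numbers.

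With a log2 fold change of at least 1 required, 2151 genes changed on MCD (29.8% higher, against 47.5%), 304 on chow (34.9%, against 46.3%) and 1335 differed between diets (43.8%, against 54.4%), fewer by construction. Relative to column totals 3138 changed on chow (83.0% higher), 5438 differed between diets (13.2% higher) and 6866 changed on MCD (20.4% higher), so the balance of directions depends on the scaling. Diet ratios of at least 2 times numbered 1766 under IgG and 324 under anti-ACBP at a CPM of 1 or more, 1223 under IgG by column totals and 260 under anti-ACBP without centring. The correlation with the diet ratio was -0.401 with the anti-ACBP groups. The 40 results of named genes kept direction and call under both scalings, and Dbi on MCD was 0.606 by column totals.

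Among the fixed lists, with a correlation of 0.05 the adjusted p no longer passed on MCD for acute phase (0.08394), glucose metabolism (0.0869) and neutrophil markers (0.05576). For the difference between diets it no longer passed for PPARalpha targets (0.1063), autophagy (0.09138), immediate early genes (0.05931), interferon response (0.07664), lipogenesis (0.07664) and red blood cell markers (0.07134). Relative to column totals it no longer passed on MCD for autophagy (0.05139) and neutrophil markers (0.08984), nor for the difference for PPARalpha targets (0.2573), autophagy (0.2434), immediate early genes (0.2434), interferon response (0.08125) and neutrophil markers (0.1993). It newly passed for ER stress (0.01498), cholangiocyte (0.01288) and macrophage markers (0.02834) on chow, red blood cell markers on MCD (0.02288) and pancreatic acinar markers for the difference (0.02472). The cause was not tested. The other 91 fixed list results with a correlation of 0.05 and 88 by column totals kept their side of the threshold. Among the added lists, the urea cycle list on MCD (0.06124) and the proteasome list for the difference (0.1030) no longer passed with a correlation of 0.05. By column totals the proteasome list no longer passed on chow (0.2332) or for the difference (0.8992), and the ribosomal protein list newly passed on chow, as higher (0.0006576), and for the difference, as lower on MCD (0.004187).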

Other observations

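The lists in the next paragraph were added after the data were examined. Values of single genes and groups are those of the authors' deposited tables.

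Complement and coagulation genes moved in opposite directions on the diets. Of 24 such genes 18 rose and 0 fell on MCD (19 and 0 adjusted over the list alone; list test adjusted p = 1.70e-14), among them C8a (1.49 ± 0.13). On chow 11 fell and 0 rose (13 and 0 adjusted over the list alone; list test adjusted p = 6.17e-13), with C4b at -0.79 ± 0.063 and C9 at -0.84 ± 0.11. The difference between diets passed for 22 of 24. Of 22 genes of the urea cycle and amino acid catabolism 8 rose and 2 fell on MCD (9 and 2 adjusted over the list alone; list test adjusted p = 0.0110, and adjusted p = 0.0612 with a correlation of 0.05). Their median of 0.18 was -0.005 relative to column totals. It lay above those of only 61.83% of 10000 random lists matched on mean expression. On chow 11 fell and 1 rose (12 and 1 adjusted over the list alone; list test adjusted p = 4.65e-12), with glycine decarboxylase Gldc at -1.08 ± 0.067.

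Of 13 tested female-biased liver genes 8 fell on MCD (12 adjusted over the list alone; list test adjusted p = 7.54e-07), with Cyp2b13 at -4.75 ± 0.54, and on chow 5 of 6 rose (5 adjusted over the list alone; list test adjusted p = 2.13e-05), with Cux2 at 2.79 ± 0.56. The list holds 18 genes, and the others were not tested on chow. The lowest mean tested there, 12.85, is taken over both groups. This favours low genes that rose, so 5 of 6 cannot stand for the whole list. Ribosomal protein genes did not pass the list test on MCD (1 of 26 rose, 0 adjusted over the list alone, adjusted p = 0.660) or on chow (0 of 26, 0 adjusted over the list alone, adjusted p = 0.223). The list passed on chow as higher relative to column totals (adjusted p = 6.58e-04), so its call depends on the scaling. Of 24 proteasome genes 1 rose on MCD (1 adjusted over the list alone; list test adjusted p = 0.472). On chow 2 fell (0 adjusted over the list alone; list test adjusted p = 0.00217), with a median of -0.12 that was 0.02 relative to column totals, where the list no longer passed (adjusted p = 0.233).

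The Mup family took 0.55% of the MCD IgG column and 1.94% of the MCD anti-ACBP column, and 10.1% and 5.17% on chow. Of 20 Mup genes 17 rose on MCD and 19 fell on chow. The antibody effect on chow had Pearson's r = 0.355 with the diet ratio under IgG across 9086 genes, with a covariance of 0.0775. The value computed from the SEs for the shared chow IgG libraries alone was 0.0122.

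Genes whose p the authors' tool withheld have group means that were not tested. On chow the muscle genes Acta1, Ckm and Myh4 had means of 236, 270 and 413 normalized counts with IgG and 14.1, 12.2 and 0 with anti-ACBP. The SEs of their log2 fold changes were 1.77, 1.64 and 3.38. Dmbt1 had means of 892 and 1.80 on MCD and of 1073 and 0.61 on chow, with SEs of 2.14 and 3.02. How many libraries carry these means is not known here, so they are not given as group differences. Srebf1, a regulator of lipid synthesis, had means of 6204 and 14520 on MCD.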
